A study of Mus musculus with 12 samples.

How the data were processed

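Total RNA was isolated from flash-frozen mouse lung tumours with a combined DNA and RNA column kit, copied from an oligo-dT primer and labelled with Cy3 or Cy5 during in vitro transcription, per the labels' protocols. Each of 12 arrays, numbered as replicates 1 to 12 in the labels, received KO RNA in one dye and WT RNA in the other. The KO RNA was in Cy5 on 6 arrays and in Cy3 on 6. The design text calls the 12 arrays biological replicates. Arrays with the same ages and sexes in the labels were taken as 1 pair, which gave 4 pairs on 3 slides of 4 arrays.

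Spot intensities and local backgrounds were extracted from the scans with Agilent Feature Extraction 10.1.1.1 under protocol GE2-v5_10_Apr08 on array design 014868, per the file headers. The deposited mean intensity of a spot and the median intensity of its local background are not normalized. The deposited flags of each spot and dye (0 or 1) record whether it was well above background, saturated or outlying. Agilent's processed intensities had been background-subtracted with spatial detrending, detrended multiplicatively and dye-normalized by linear and lowess factors, per the file headers. The series matrix holds the authors' log2 ratio per probe, made with limma per the submitters' processing notes. Their version and normalization steps are not given in the sources used here. Set against the scanner values over 41174 matched probes, each column was a log2 ratio of KO over WT with the swapped arrays already turned. The slope was between 1.005 and 1.055, the correlation across probes well above background in both dyes between 0.9925 and 0.999, and the column median between -0.011 and 0.0077. How the authors centred these ratios stays unknown.

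Probe names follow the array annotation on build mm7, per the file headers. Of 41174 probes (43379 spots without controls), 22951 were named through a RefSeq accession in a reference gene table of assembly GRCm38.p6. A further 11480 kept the name in the file, and 6743 had no gene name and were left out of gene-level tests. Since the builds differ, the reference table was used only for names and for which genes neighbour each other.

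The analysis used R 4.3.3 with limma 3.58.1, statmod 1.5.0 and data.table (version 1.17.8). Mean signals were corrected for local background with normexp (offset 50) and normalized within each array by loess, with control spots and outlier-flagged spots (86 to 828 per array) at weight 0. Spots whose local background was itself marked as outlying took the median local background of that array and dye. There were 901 to 1240 such spots per array in red and 341 to 2117 in green, with backgrounds of up to 146735 and 202323. This step was chosen after a first result was seen. Without it the correction failed on replicates 2, 4, 9 and 12, whose correlation with the authors' ratios across kept probes was 0.861, 0.758, 0.779 and 0.892, against 0.996, 0.997, 0.995 and 0.995 with it. Spots of a probe were averaged, and outlier-flagged spots were left out. Probes were kept where they were well above background for KO or for WT RNA on at least 6 of 12 arrays, which left 35562 probes. Each gene was represented by its kept probe of highest mean signal, for 20403 genes.

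The model had a dye term and a coefficient for KO over WT, with the pair as a random block (consensus correlation -0.028) and Benjamini-Hochberg adjustment. That correlation came from red over green ratios, where a KO over WT difference of pair A or B changes sign with the dye. The block therefore could not absorb such a difference, and the fit in effect took the 12 arrays as independent. A second model gave each pair its own coefficient, and an F test over their differences compared the pairs. Shifts of 45 gene lists were tested with cameraPR at a preset correlation of 0.01, then with a correlation estimated per list, and with fry. The groups, tests, lists, marker genes, the alternatives apart from those named below as added and the rule for named genes were fixed before the data were examined. That rule took Dnmt3a, Dnmt1 and Dnmt3b in any case. It then took the 12 largest rises and 12 largest falls among called genes with the same sign on at least 10 of 12 arrays. Xist, Tsix, Y-linked genes, immune receptor segments and clone names were left out there, and other X-linked genes were kept. It also took up to 4 members of smallest p for each list described, the 6 genes of smallest p between pairs, and sex-linked genes as a check of labels. Of 153 named genes, 57 had more than 1 kept probe, and in 1 of them (Abca3) a called probe went the opposite way. Other kept probes of some named genes moved far less than the probe used, among them those of Rrp7a, Amph, Hmga2, Cdh11 and Grb10.

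Alternatives covered background correction, normalization, probe filter, probes per gene, dye term, block, arrays left out singly and by pair, array weights, variance model, threshold and the series matrix values. Added after the data were seen were the local backgrounds as deposited, a dye term per slide, leaving out replicates 5 and 11, and fits within each slide. The mean of each pair as 1 value, also used for the patterns of signs by pair, was taken without a dye term. Pairs C and D had opposite dye orientations, so dye shifts entered their means with opposite signs and could widen the spread. Where several single arrays each ended the call of a gene when left out, the ratio and adjusted p are given for the array with the highest adjusted p. Levels per dye were taken after loess and Aquantile, and can carry dye bias on single arrays. The fit, the F test between pairs and both list tests were tested on simulated data of 20403 genes, and the repair of local backgrounds and the tests of sign patterns, of neighbouring genes and of levels per dye were not. Of 200 genes changed on all arrays, the fit called 94% of those changed by 1 (log2) and 71% of those changed by 0.5. The same data held 200 genes changed in pair B alone and a list of 20 genes shifted by -0.5. Of all calls of the fit, 5.16% were genes simulated as unchanged. The simulated spread was drawn independently for each gene and array. These shares therefore do not give the rate of false calls where arrays of a pair share animals or genes move together. The F test called 86% of 200 genes changed by 2 in pair B alone.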

Results

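Messenger RNA was compared between lung tumours labelled as knocked out (KO) for Dnmt3a, an enzyme that places new methyl groups on DNA, and lung tumours labelled as wild type (WT) for it. The tumours arose in mice of mixed C57/129 background whose airways received a Cre-carrying adenovirus, which was given to switch on a mutant K-ras allele and, in the KO animals, to remove the conditional Dnmt3a alleles, per the labels. Each of 12 two-colour Agilent arrays carried RNA of a KO tumour and RNA of a WT tumour, with the KO RNA in Cy5 on 6 arrays and in Cy3 on the other 6. The labels hold 4 combinations of ages and sexes, called pairs A to D here. Pair A (4 arrays) set a KO animal of age 47.7 against a WT animal of age 42.6, and pair B (4 arrays) set ages 27 and 41.3 side by side, in a unit that the labels do not give. Pair C (2 arrays, KO age 27, WT age 47.6) was the only one with a female WT animal, and pair D (2 arrays) had ages 29.1 and 37.3. Nothing in the labels says whether the arrays of a pair came from separate animals, so p-values measure only the spread between these samples, which may be technical. The KO animals of pairs B and C have the same age and sex in the labels. These pairs may therefore share a KO animal, and the 4 pairs may not be independent. In pairs B, C and D the KO animal was younger than the WT animal, and only pair A had the older KO animal. Genotype and age are therefore partly confounded in the results below.

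The arrays of pair A lay on slide 1, those of pair B on slide 2, and those of pairs C and D on slide 3. Between 81.7% and 89.6% of the 41174 probes were well above background on slides 1 and 2, against 59.0% to 72.2% on slide 3. The median signal over local background ranged from 3.69 to 10.0 for KO RNA and from 3.49 to 7.28 for WT RNA, and 0 probes were saturated. The number of arrays limits the precision of each ratio. Across genes, which are not independent replicates, the KO over WT ratios of arrays of one pair correlated at a mean of 0.34 and those of different pairs at 0.24 (single values from -0.13 to 0.61).

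Dnmt3a itself was lower in the KO tumours. Its brightest probe gave a log2 KO over WT ratio of -0.21 ± 0.042 (SE, n = 12 arrays, limma adjusted p = 0.0107), below 0 on 12 of 12 arrays, with single arrays between -0.43 and -0.057. Both other Dnmt3a probes were lower too, at -0.56 ± 0.070 and -0.25 ± 0.047 (limma over all probes, adjusted p = 0.00123 and 0.00931). At the first of these, WT RNA was well above background on 12 arrays and KO RNA on 8. In pairs C and D the KO RNA was so on 0 of 2 arrays each. Only lower bounds of the fall can be given there, at 1.23-fold and 1.31-fold. Dnmt1, which copies methylation onto new DNA strands, stood at -0.056 ± 0.064, adjusted p = 0.645 (0.061 without pair A), and Dnmt3b, the related de novo enzyme, at 0.074 ± 0.081, adjusted p = 0.629. Among 18 measured genes of the DNA methylation machinery, Uhrf2 rose (0.76 ± 0.15, higher on 12 of 12 arrays), while Dnmt3a, Gadd45g (-0.63 ± 0.14) and Mbd1 (-0.40 ± 0.11) fell. Adjusted over the list alone, 1 rose and 3 fell, and the list as a whole did not shift (median -0.016, adjusted p = 0.832). The Mbd1 call ended with any of 10 single arrays left out, the highest adjusted p being 0.0899 (-0.37 without replicate 7). Both other Mbd1 probes were lower too, at -1.62 and -0.32 (limma over all probes, adjusted p = 0.00146 and 0.0485). The part of Dnmt3a that Cre removes is not given in the sources used here, and a probe outside it checks nothing. The brightest probe was 1.16-fold lower, so most of its signal remained, and these probes do not establish the removal. The Dnmt3a call ended with the mean of each pair as 1 value (-0.23, adjusted p = 0.179), with pairs A and B alone (-0.17, adjusted p = 0.151), without pair A (-0.22, adjusted p = 0.0502) and without pair B (-0.23, adjusted p = 0.0727). It also ended with local backgrounds as deposited (-0.15, adjusted p = 0.0677) and within slides 1, 2 and 3 (-0.18, -0.16 and -0.29, adjusted p = 0.460, 0.326 and 0.227). Over its alternatives the ratio lay between -0.34 and -0.15 and the adjusted p between 0.000462 and 0.460.

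The genes that rose furthest in KO tumours were Dlk1, an imprinted transmembrane ligand (log2 ratio 2.46 ± 0.58, SE over 12 arrays, adjusted p = 0.0215), and Amph, which bends membranes during endocytosis (2.40 ± 0.43, adjusted p = 0.00654). Lman1l (2.37 ± 0.36, adjusted p = 0.00252) and Cltrn (2.25 ± 0.50, adjusted p = 0.0162) followed. Tpbg, an oncofetal surface glycoprotein, rose by 1.84 ± 0.19 and was higher on 12 of 12 arrays, and Sox9, a transcription factor of the embryonic lung, rose by 1.79 ± 0.46. The other large rises were Shisa2 (1.96 ± 0.44), Moxd1 (1.95 ± 0.31), Lrrn1 (1.89 ± 0.46), the microvillus protein Vil1 (1.73 ± 0.43), the platelet chemokine Pf4 (1.73 ± 0.39) and the secreted serpin Serpinf1 (1.73 ± 0.35), each higher on at least 10 of 12 arrays. Rrp7a, named for ribosomal RNA processing, fell furthest (-2.50 ± 0.23, adjusted p = 0.000191, lower on 12 of 12 arrays), ahead of the anion exchanger Slc26a4 (-2.42 ± 0.46), the kininogen gene Kng1 (-2.17 ± 0.41) and Fxyd4, which modulates the sodium pump (-2.13 ± 0.39). Jchain, which joins the units of secreted antibodies, fell (-2.03 ± 0.53), as did the pericyte regulator Rgs5 (-1.66 ± 0.31) and the mucosal chemokine Cxcl17 (-1.65 ± 0.35). The xenobiotic oxidase Cyp1a1 (-1.60 ± 0.34), the transcription factors Evi1 (-1.56 ± 0.20) and Irx1 (-1.55 ± 0.27), the glutathione transferase Gsto1 (-1.54 ± 0.41) and the actin-binding Ablim3 (-1.48 ± 0.24) completed the 12 largest falls. The Rgs5 ratio was -0.99 without pair A (-3.00 in that pair, -0.81 in pair B), and the Cyp1a1 ratio -0.88 without pair B (-3.04 in that pair, -0.66 in pair A). The WT RNA of Shisa2 and the KO RNA of Cyp1a1 were well above background on 7 of 12 arrays each. Other kept probes barely moved for Rrp7a (-0.10), Amph (0.025), Lrrn1 (0.023) and Ablim3 (-0.039 and -0.040). The other Lman1l probe was at 0.24, and none of these had a call over all probes. Those of Dlk1 (2.14), Vil1 (1.79), Serpinf1 (0.98), Tpbg (0.75 and 0.29) and Sox9 (1.61 and 0.18) rose with a call. Those of Jchain (-2.06), Rgs5 (-0.93) and Irx1 (-0.69) fell with a call. Leaving out single arrays ended the calls of Lrrn1 (1.73 without replicate 9, adjusted p = 0.0602), Sox9 (1.77 without replicate 12, adjusted p = 0.0655), Vil1 (1.65 without replicate 9, adjusted p = 0.0592), Jchain (-1.82 without replicate 9, adjusted p = 0.0692) and Gsto1 (-1.45 without replicate 3, adjusted p = 0.0764).

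**Figure D1:**
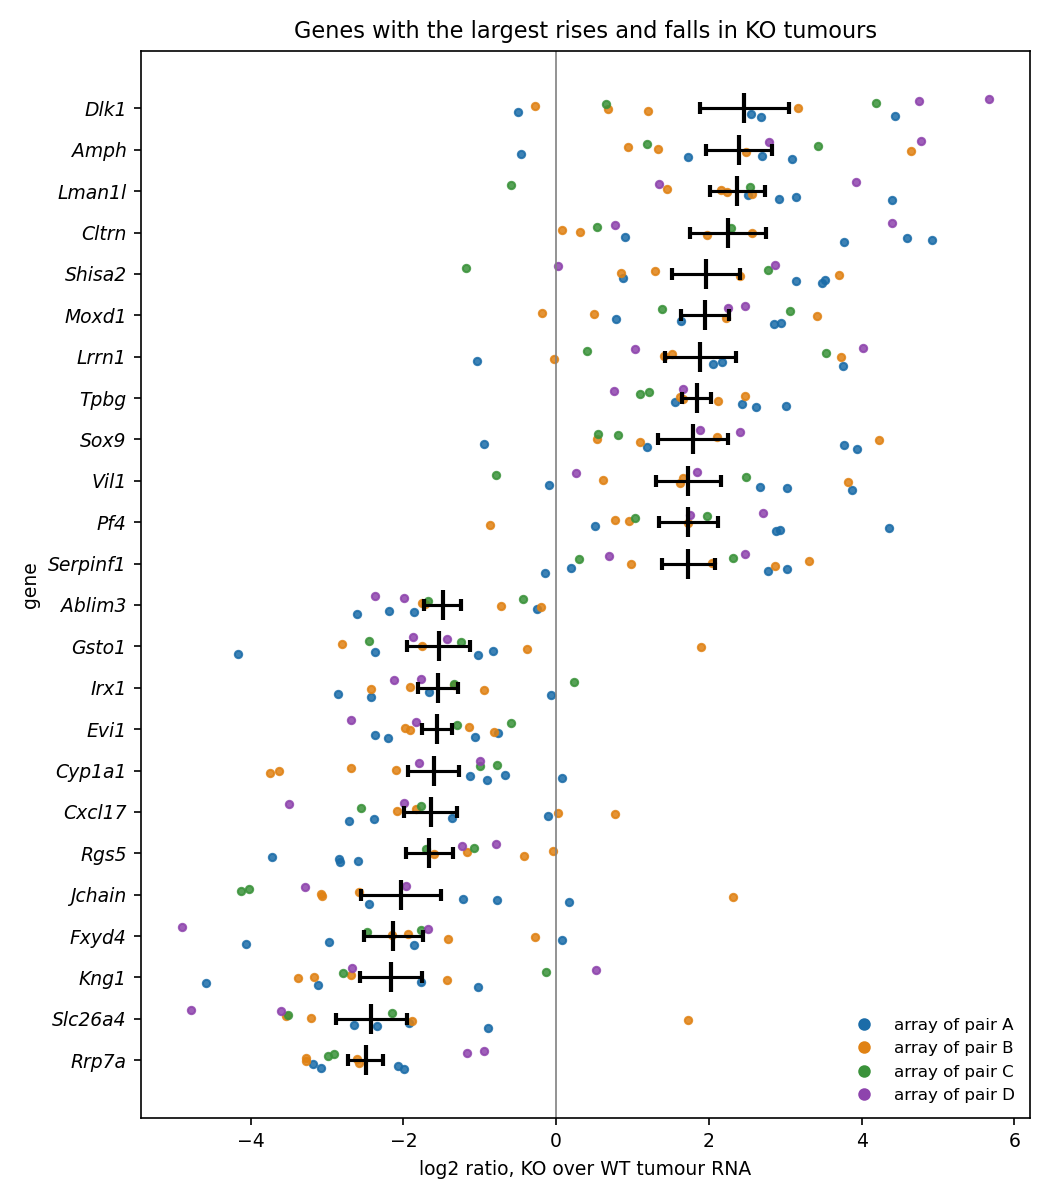
Log2 KO over WT ratio of the 12 genes with the largest rise and the 12 with the largest fall, one point per array coloured by pair, with the fitted ratio and its SE. Tpbg and Cltrn lay above 0 and Rrp7a, Rgs5, Evi1 and Ablim3 below 0 on 12 of 12 arrays, while Dlk1 was above 0 on 10.

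In all, 2173 of 20403 genes changed at an adjusted p under 0.05 in limma, 1077 higher and 1096 lower in KO tumours, and 5285 had an unadjusted p under 0.05. Of the changed genes, 146 had an absolute log2 ratio of at least 1 (74 higher, 72 lower), and 2073 had the same sign on at least 10 of 12 arrays. Erg, Grb10, Pecam1 and Ramp2 were the named genes that kept their call under each of the 36 alternative settings that refitted single genes across slides, and they lost it within each slide. Of the 115 named genes with a call besides Dnmt3a, 79 kept it with each single array left out, and 28 also with each pair left out. Single arrays moved the log2 ratios of the 115 by at most 1.33 times, and 12 moved by over 1.5 times with a pair left out. The count was 2205 with the 12 arrays taken as independent. It fell to 546 with pairs A and B alone, and to 48 (18 higher, 30 lower) with the mean of each pair as 1 value, taken without a dye term. It was 696 without pair A, 1024 without pair B, 1259 without pair C, 1265 without pair D, 1394 without replicate 3, 1448 without replicate 7 and 1387 without replicate 12. Limma called 0 genes within slide 1, 1 within slide 2 (Rrp7a) and 0 within slide 3, where 3224, 3182 and 3278 genes had an unadjusted p under 0.05. The split of calls moved to 1283 higher and 647 lower with median centring, and to 890 higher and 594 lower with local backgrounds as deposited.

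Blood vessel genes fell in KO tumours. Of 20 endothelial markers, 17 fell and 0 rose (19 lower when adjusted over the list alone), with a median log2 ratio of -0.67 and a median below 0 on 12 of 12 arrays. The adhesion molecule Pecam1 (-0.65 ± 0.055, SE) and the junctional cadherin Cdh5 (-0.82 ± 0.070) fell, each lower on 12 of 12 arrays. So did the endothelial transcription factor Erg (-0.997 ± 0.087) and the receptor partner Ramp2 (-0.95 ± 0.087), also lower on 12 of 12. The endothelial median was -0.59 in pair A, -0.61 in pair B, -0.71 in pair C and -0.99 in pair D. Limma's set test gave the list an adjusted p of 2.06e-44, and 4.99e-08 with an estimated correlation. Within slides 1, 2 and 3 the median was -0.59, -0.61 and -0.91. None of the 20 markers belonged to another list.

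Pericyte, lymphatic and angiogenesis genes were lower as well. Of 12 smooth muscle and pericyte genes 6 fell (6 adjusted over the list alone), among them the receptors Pdgfrb (-0.88 ± 0.093) and Notch3 (-0.81 ± 0.13). The list's median was -0.36 (adjusted p = 6.18e-05, and 0.0133 with an estimated correlation). Of 5 lymphatic vessel genes 4 fell (4 adjusted over the list alone), including the hyaluronan receptor Lyve1 (-0.92 ± 0.16), Reln (-0.41 ± 0.084) and Mmrn1 (-0.64 ± 0.15). The lymphatic median was -0.41 (adjusted p = 0.000478, and 0.0133 with an estimated correlation). Of 29 angiogenesis genes 8 fell and 1 rose (11 and 2 adjusted over the list alone). The angiogenesis median was -0.21 (adjusted p = 3.52e-06, and 0.000344 with an estimated correlation). The lymphatic growth factor Vegfc (-1.01 ± 0.080), the endothelial nitric oxide synthase Nos3 (-0.58 ± 0.048) and the sphingosine phosphate receptor S1pr1 (-1.03 ± 0.098) fell. The Notch ligand Jag1, singled out after its value was seen, rose (0.54 ± 0.15). Within slide 3 the lymphatic median was -0.50, without a call (adjusted p = 0.277). The Jag1 call ended with any of 6 single arrays left out, among them replicate 12 (0.50, adjusted p = 0.0812). On replicate 11, the array with the lowest airway medians, the endothelial (-1.14), lymphatic (-0.91) and smooth muscle and pericyte (-0.93) medians were also the lowest of the 12 arrays. Without that array these medians were -0.63, -0.37 and -0.30, each with a call.

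**Figure D2:**
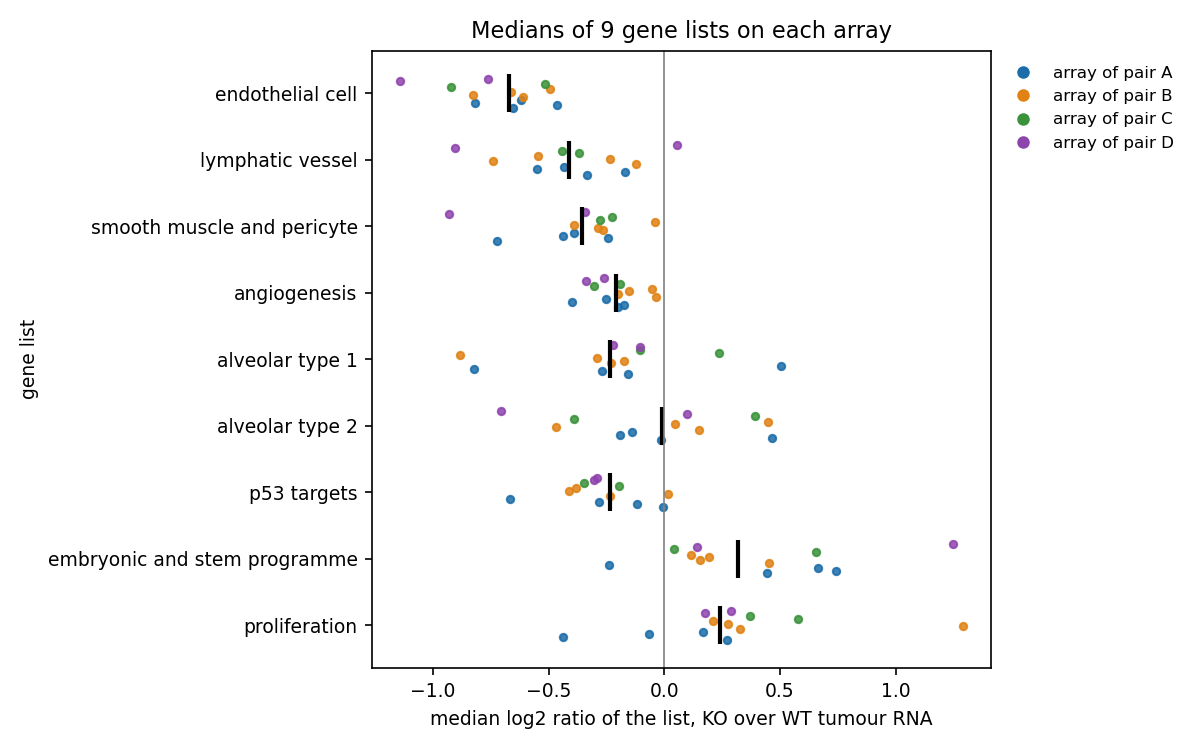
Median log2 KO over WT ratio of 9 gene lists, one point per array coloured by pair, with a black bar at the median of the fitted ratios. The endothelial points lay below 0 on 12 of 12 arrays, and the alveolar type 2 points on 6.

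Of the 45 lists, 18 shifted at an adjusted p under 0.05 with the preset correlation, 4 higher and 14 lower in KO tumours. The endothelial, smooth muscle and pericyte, lymphatic and angiogenesis lists kept that call with an estimated correlation, and the other 14 did not. The endothelial, smooth muscle and pericyte, angiogenesis and p53 lists kept the call within each of the 3 slides, and the other 14 lost it within at least 1. With single arrays or pairs left out, 9 of the 18 lists kept their call throughout, among them the endothelial, pericyte, lymphatic, angiogenesis, p53 and motility lists. The rotation test fry, which asks whether the genes of a list move on balance one way and compares them with no other genes, called 15 lists, 12 of them among the 18. The other 3 were the Wnt target, immediate early and heat shock, and neuroendocrine lists (fry adjusted p = 0.0313, 0.0175 and 0.0488). After results were seen, the count of 18 was set against 100 drawn assignments of KO and WT signs to the 12 arrays, the real one included. With other signs, 1 assignment called 22 lists, and assignments with the real sign on only 6 arrays called up to 11. The preset test can thus call many lists without a KO over WT difference, and its count alone does not show one.

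Growth-related lists were higher in KO tumours with the preset correlation. Of 25 proliferation genes 4 rose (6 adjusted over the list alone), including the thymidylate synthase Tyms (0.49 ± 0.044), the mitotic kinase Aurkb (0.54 ± 0.14) and the cyclin Ccnb2 (0.60 ± 0.16). The proliferation median was 0.24 (adjusted p = 7.50e-05, and adjusted p = 0.490 with an estimated correlation). Within slide 1, which held pair A, that median was -0.038, and without replicate 6 it was 0.11 (adjusted p = 0.000248), without pair A 0.45 and without pair B 0.13. By pair the proliferation median was -0.032 in pair A, the only pair with the older KO animal. It was 0.51, 0.59 and 0.13 in pairs B, C and D, where the KO animal was younger. A part of age in the proliferation result was not tested and stays open. Of 17 embryonic and stem genes 5 rose (6 adjusted over the list alone), among them the chromatin protein Hmga2 (1.61 ± 0.27), Dlk1, Sox9, Id2 (0.98 ± 0.24) and Sox4 (0.70 ± 0.17). Their median was 0.32 (adjusted p = 0.00364, and adjusted p = 0.113 with an estimated correlation), and the median was 0.16 without pair A, 0.49 without pair C and 0.19 without replicate 12. Of 19 genes of Ras-MAPK output 6 rose and 3 fell (8 and 4 adjusted over the list alone), at a median of 0.28 (adjusted p = 0.0303, and adjusted p = 0.158 with an estimated correlation). The growth factor Ereg (0.31 ± 0.052) and the transcription factors Etv1 (0.58 ± 0.11) and Egr1 (0.81 ± 0.17) rose, whereas the transcription factor Etv5 (-0.59 ± 0.13), the cyclin Ccnd1 (-0.58 ± 0.15) and Phlda1 (-0.58 ± 0.17, singled out after its value was seen) fell. The Ras-MAPK list lost its call without replicate 6 (0.21, adjusted p = 0.0692) or 11 (0.23, adjusted p = 0.115) and without pair B (0.23, adjusted p = 0.0851), C (0.29, adjusted p = 0.0627) or D (0.22, adjusted p = 0.0611). The Ccnd1 ratio was -0.27 without pair A (adjusted p = 0.240) and -0.85 without pair B. Calls of single genes ended without single arrays for Aurkb (0.53 without replicate 9, adjusted p = 0.0672), Ccnb2 (0.55 without replicate 9, adjusted p = 0.0769), Sox9 (1.77 without replicate 12, adjusted p = 0.0655), Id2 (0.95 without replicate 3, adjusted p = 0.0520), Sox4 (0.63 without replicate 12, adjusted p = 0.0557), Ccnd1 (-0.57 without replicate 12, adjusted p = 0.0611) and Phlda1 (-0.55 without replicate 3, adjusted p = 0.101). The Ereg ratio turned to -0.11 (adjusted p = 0.676) with the mean of its probes. Among 26 ribosomal protein genes 4 rose (4 adjusted over the list alone), including Rpl3 (0.57 ± 0.072) and Rpl7 (0.33 ± 0.061). The ribosomal median was 0.15 (adjusted p = 0.00108, and adjusted p = 0.490 with an estimated correlation), and -0.024 within slide 2. It was 0.26 without pair B, and the call ended without pair A (0.074, adjusted p = 0.0888) and without pair D (0.079, adjusted p = 0.0775).

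Targets of p53 were lower as a list with the preset correlation. Of 16 measured, 6 fell and 0 rose (7 lower adjusted over the list alone), including the cell cycle inhibitor Cdkn1a (-0.76 ± 0.12), the pro-apoptotic Pmaip1 (-1.43 ± 0.23) and Phlda3 (-0.52 ± 0.10). The median of the p53 list was -0.23 (adjusted p = 0.000455, and adjusted p = 0.0581 with an estimated correlation). Of 27 genes of cell motility and epithelial-mesenchymal transition 6 fell and 1 rose (8 and 1 adjusted over the list alone), at a median of -0.23 (adjusted p = 0.00108, and adjusted p = 0.327 with an estimated correlation). The repressor Zeb1 (-0.50 ± 0.062), the calcium-binding S100a4 (-1.25 ± 0.19) and the growth factor Tgfb2 (-0.65 ± 0.14) fell, and the guidance molecule Sema3c rose (0.51 ± 0.13). Of 20 detoxification genes 6 fell (8 lower and 1 higher adjusted over the list alone), among them Cyp1a1, Gsto1 and the glutathione-synthesis enzyme Gclc (-1.04 ± 0.28). The detoxification median was -0.50 (adjusted p = 0.0222, and adjusted p = 0.490 with an estimated correlation). Of 18 hypoxia and glycolysis genes Adm (-0.45 ± 0.087) and Ankrd37 (-0.68 ± 0.17) fell (4 lower and 1 higher adjusted over the list alone). The hypoxia median was -0.17 (adjusted p = 0.0220, and adjusted p = 0.490 with an estimated correlation), and 0.022 within slide 2. Without pair B it was -0.33, and the call ended without replicate 2 (-0.11, adjusted p = 0.0719) or 10 (-0.14, adjusted p = 0.0626) and without pair A (-0.11, adjusted p = 0.208) or C (-0.12, adjusted p = 0.187). The detoxification call ended without replicate 7 (-0.44, adjusted p = 0.0694) or 10 (-0.42, adjusted p = 0.0983) and without pair C (-0.35, adjusted p = 0.198). The Tgfb2 ratio was -0.37 without pair A, and single arrays ended the calls of Sema3c (0.47 without replicate 9, adjusted p = 0.0568), Gsto1 (-1.45 without replicate 3, adjusted p = 0.0764), Gclc (-0.98 without replicate 9, adjusted p = 0.0861) and Ankrd37 (-0.65 without replicate 12, adjusted p = 0.0576).

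Fibroblast, macrophage, red cell and interferon lists were lower with the preset correlation. Of 20 fibroblast and matrix genes 5 fell, including elastin (Eln, -0.58 ± 0.10), Postn (-0.81 ± 0.16) and Fbn1 (-0.46 ± 0.10, n = 11 arrays), and the collagen-binding Lum rose (1.13 ± 0.27). Adjusted over the list alone, 6 fibroblast genes fell and 1 rose, at a median of -0.30 (adjusted p = 0.0119, and adjusted p = 0.490 with an estimated correlation). Of 19 macrophage genes Itgax alone fell (-0.54 ± 0.13; 1 lower adjusted over the list alone) and Mpeg1 stood at -0.52 ± 0.16 (adjusted p = 0.0549). The macrophage median was -0.28 (adjusted p = 0.0119, and adjusted p = 0.490 with an estimated correlation). Of 9 red cell and platelet genes 5 fell, among them the haemoglobin chain Hba-a1 (-1.47 ± 0.34) and its chaperone Eraf (-1.15 ± 0.23), while the platelet gene Pf4 rose. The counts adjusted over the list alone were also 5 and 1. The red cell and platelet median was -0.21 (adjusted p = 0.0340, and adjusted p = 0.0730 with an estimated correlation), and 0.037 within slide 2. Of 20 interferon response genes 3 fell (4 adjusted over the list alone), including Usp18 (-0.63 ± 0.063) and Ifit3 (-0.59 ± 0.12). The interferon median was -0.14 (adjusted p = 0.00364, and adjusted p = 0.439 with an estimated correlation), and -0.21 without pair B. The red cell and platelet call ended without replicate 1 (-0.17, adjusted p = 0.0581) or 4 (-0.21, adjusted p = 0.0699) and without pair A (-0.20, adjusted p = 0.208) or C (-0.27, adjusted p = 0.0525). The Hba-a1 ratio was -0.90 without pair A (adjusted p = 0.268) and -2.26 without pair B, and single arrays ended the calls of Lum (1.09 without replicate 9, adjusted p = 0.0556) and Itgax (-0.49 without replicate 12, adjusted p = 0.0604). The macrophage call ended without pair C (-0.18, adjusted p = 0.0627), and the fibroblast call without pair A (-0.19, adjusted p = 0.243) or D (-0.26, adjusted p = 0.0647), with a fibroblast median of -0.45 without pair B.

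Gene families that DNA methylation is known to act on gave small or mixed shifts. Among 21 imprinted genes Grb10, a growth-restraining adaptor, fell (-0.65 ± 0.052, lower on 12 of 12 arrays), while Nnat (0.97 ± 0.22), Sgce (0.87 ± 0.21) and Dlk1 rose, with the same counts adjusted over the list alone. Both other Grb10 probes barely moved (-0.0074 and -0.051, without a call), whereas the other Sgce (0.85) and Dlk1 (2.14) probes rose with a call. The imprinted list did not shift (median -0.045, mean 0.18, test direction lower, adjusted p = 0.993). Of 20 germline genes Dppa5a rose (0.38 ± 0.091; 1 higher adjusted over the list alone), and Piwil2 stood at -0.15 ± 0.086, adjusted p = 0.304 (list median -0.022, mean 0.0062, test direction lower, adjusted p = 0.993). The Piwil2 ratio was -0.065 without replicate 7. Of 16 clustered protocadherins 3 fell, including Pcdhb3 (-0.20 ± 0.039) and Pcdhb9 (-0.20 ± 0.043), and 7 when adjusted over the list alone. The protocadherin median was -0.10 (adjusted p = 0.0121, and adjusted p = 0.431 with an estimated correlation). Of 30 Hox genes 4 fell (5 adjusted over the list alone), among them Hoxa5 (-0.38 ± 0.052) and Hoxa7 (-0.62 ± 0.14). The Hox median was -0.028 (adjusted p = 0.0380, and adjusted p = 0.327 with an estimated correlation). The Hox call ended without pair A (-0.038, adjusted p = 0.0642), B (-0.023, adjusted p = 0.0870), C (-0.040, adjusted p = 0.0525) or D (-0.018, adjusted p = 0.177). It also ended without replicate 1, 3, 6, 11 or 12 (medians -0.019, -0.023, -0.024, -0.024 and -0.029, adjusted p = 0.0581, 0.0816, 0.0638, 0.0578 and 0.0825). The protocadherin call ended without pair D (-0.076, adjusted p = 0.0785). Sgce lost its call without pair A (0.51, adjusted p = 0.134), and without replicate 3 or 12 (0.82, adjusted p = 0.0546 for the latter).

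Over the 12 arrays, markers of the lung epithelium did not shift as lists. Of 17 alveolar type 2 genes Etv5 and the lysosomal Lamp3 (-0.78 ± 0.18, n = 11 arrays) fell and the lipid transporter Abca3 rose (0.36 ± 0.10). Adjusted over the list alone 2 were higher and 2 lower, at a median of -0.012 (adjusted p = 0.993). Single arrays ended the calls of Lamp3 (-0.72 without replicate 12, adjusted p = 0.0556), Abca3 (0.33 without replicate 10, adjusted p = 0.0784) and Vil1 (1.65 without replicate 9, adjusted p = 0.0592). Another Abca3 probe was lower, at -0.18 ± 0.037 (limma over all probes, adjusted p = 0.0139). Of 10 alveolar type 1 genes Spock2 fell (-0.87 ± 0.14; 3 lower adjusted over the list alone) and Igfbp2 stood at -0.89 ± 0.27, adjusted p = 0.0546, with a list median of -0.23 (adjusted p = 0.0977). The alveolar type 1 list was lower within slide 1 (-0.12, adjusted p = 0.0125) and slide 2 (-0.31, adjusted p = 0.000412), and stood at -0.19 within slide 3 (adjusted p = 0.722). It passed the threshold without replicate 4 (-0.34, adjusted p = 0.0316) or 9 (-0.31, adjusted p = 0.0494) and without pair A (-0.32, adjusted p = 0.0325). Without pair B its median was -0.14. Of 12 club cell genes, of the secretory airway cell, 0 changed in limma, also when adjusted over the list alone, and 2 had an unadjusted p under 0.05. Aldh1a1 stood at -0.73 ± 0.23, adjusted p = 0.0627 and Kcnj15 at -0.40 ± 0.15, adjusted p = 0.116 (list median -0.21, adjusted p = 0.509), and the club list was lower within slide 3 (-1.05, adjusted p = 0.00135), which held replicate 11. Of 14 ciliated cell genes 0 changed likewise (0 at an unadjusted p under 0.05), with Tekt2 at -0.56 ± 0.26, adjusted p = 0.209 and Dnaic1 at -0.087 ± 0.058, adjusted p = 0.388 (list median -0.16, adjusted p = 0.564). Of 17 gastric and gut genes, which mark another epithelium, Foxa3 (0.44 ± 0.10) and Vil1 rose, with the same count adjusted over the list alone. That list had a median of -0.0036, a mean of 0.30, a test direction of higher and an adjusted p of 0.279, and within slide 2 a median of 0.85 (adjusted p = 7.60e-05). On replicate 11, an array of pair D, the club median was -3.08 and the ciliated median -2.07, and the median log2 level of club genes was 17.1 in the WT RNA and 11.6 in the KO RNA. Without replicate 11 the club median was -0.0038 and the ciliated median 0.023. The club median was 0.056 without pair D and -0.42 without pair B.

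**Figure D3:**
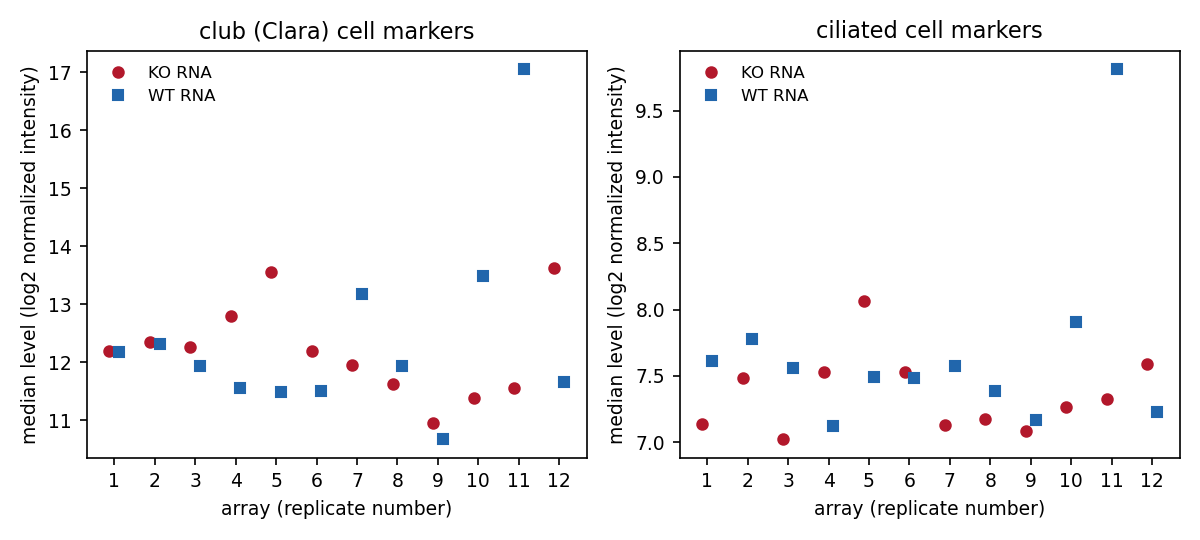
Median log2 level of the club and ciliated cell lists in the KO and WT RNA of each of the 12 arrays. The WT RNA of replicate 11 stood highest in both lists, at 17.1 and 9.81.

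The 27 lists without a call had adjusted p-values from 0.0759 to 0.996 over the 12 arrays, and 6 were lower within slide 3, namely the club cell and cytokine lists, plasma cells (-0.33, adjusted p = 1.71e-05), T cells (-0.10, adjusted p = 0.000967), neutrophils (-0.18, adjusted p = 0.0102) and MHC class II (-0.20, adjusted p = 0.0411). With single arrays or pairs left out, the median changed sign in 16 of the 27. The plasma cell list passed the threshold without replicate 5 (-0.18, adjusted p = 0.00270) and without pair B (-0.23, adjusted p = 0.0179). For the basal and squamous list the median was -0.032, the mean -0.097 and the test direction higher. For MHC class II the median was 0.051, the mean -0.0066 and the direction higher, and for mesothelium they were 0.0025, -0.19 and higher.

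The 4 pairs were then compared with each other. Pttg1, which guards against early separation of chromosomes, was -1.20 in pair A, 1.91 in pair B, 0.014 in pair C and 0.37 in pair D (limma F test, adjusted p = 1.34e-05). The phospholipase Pla2g4b was 2.37 in pair A and -1.50 in pair C (adjusted p = 7.47e-05), and the vesicle fusion gene Bet1l was 0.83 in pair A and -0.56 in pair D (adjusted p = 0.00162). Ywhaz, a 14-3-3 adaptor, was -2.29 in pair A and 1.25 in pair C (adjusted p = 0.00162), and the interferon-inducible Ifi202b was -2.86 in pair A and 0.0084 in pair B (adjusted p = 0.00293). Rrp7a was below 0 in each pair but at -0.61 in pair D against -3.40 in pair C (adjusted p = 0.00119), and Hba-a1 ranged from -2.48 in pair A to 0.11 in pair B (adjusted p = 0.0289). In all, 68 of 19822 genes differed between pairs (2432 at an unadjusted p under 0.05), and the count was 168 with median centring and 16 with local backgrounds as deposited. Over the 12 arrays Pttg1 stood at 0.30 and Pla2g4b at 0.35, without a call, and at -0.55 without pair B and -0.56 without pair A. These ratios rest on 1 probe per gene. Over the 12 arrays the Ywhaz probe used was at -0.24 ± 0.44 (SE) and its other kept probes at -0.096 ± 0.19 and 0.017 ± 0.028. Those of Pla2g4b were at -0.23 and -0.33 and those of Bet1l at 0.23 and 0.16, all without a call. Other probes were not compared between pairs. The spread behind the F test between pairs is that between arrays of a pair. Pairs A and B lay on slides of their own, pairs C and D shared a slide, and C and D each had the KO RNA in a single dye. The F test therefore cannot tell differences between animals from those between slides or dye orientations.

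Sex-linked genes checked the labels of pair C, the pair with a female WT animal. On both arrays of that pair the WT RNA of the Y-linked Ddx3y, Uty and Eif2s3y was not well above background, so that only lower bounds can be given. Ddx3y was at least 10.2-fold, Uty at least 2.55-fold and Eif2s3y at least 36.4-fold higher in the KO RNA of pair C. Each bound sets the mean KO level against, per array, the higher of the WT level and the lowest signal well above background. It is taken per dye after loess and Aquantile and is open to dye bias, since pair C had 1 dye orientation. Ddx3y and Uty differed between pairs (adjusted p = 0.00293 and 0.0190), and Eif2s3y had no call between pairs (adjusted p = 0.0509). Kdm5d, well above background in both RNAs, was 1.57 in pair C, without a call between pairs (adjusted p = 0.128). Xist, made from the inactive X chromosome, had a ratio of -0.080 at its brightest probe over the 12 arrays, but another Xist probe was at least 49.0-fold lower in the KO RNA of pair C, which was not well above background there.

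**Figure D4:**
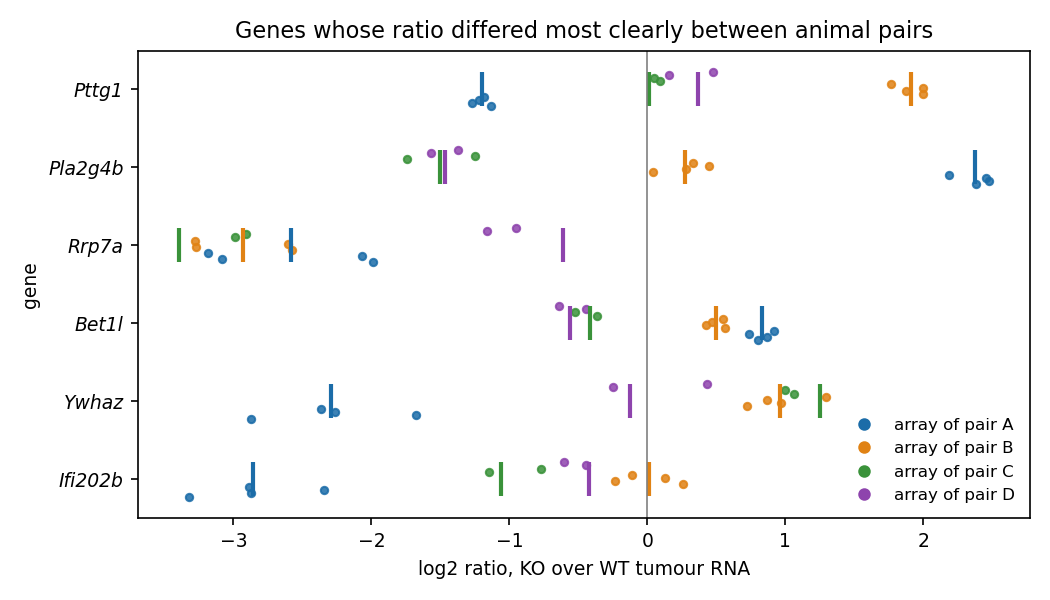
Log2 KO over WT ratio in pairs A to D of the 6 genes with the smallest p between pairs, one point per array and a vertical bar at the fitted ratio of each pair. Pttg1 had opposite signs in pairs A and B, at -1.20 and 1.91.

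Within single pairs, limma called 1024 genes in pair A, 227 in pair B, 22 in pair C and 60 in pair D, and 4220, 2825, 2135 and 3116 genes had an unadjusted p under 0.05. Pairs A and B shared 101 called genes, 96 of them in the same direction, against 11.7 for independent lists. The fit used the same estimate of the spread of a gene for both pairs. Their lists would therefore overlap somewhat more than independent ones even without a common difference, and 11.7 is only a rough guide. Pecam1 was -0.59, -0.61, -0.60 and -0.88 in pairs A, B, C and D, and Tpbg was 2.40, 1.97, 1.15 and 1.22. Pairs C and D were each hybridised in 1 dye orientation, so their ratios rest on a dye term estimated from the other arrays. With median centring pair C had 94 calls and pair D 1635, and with local backgrounds as deposited the pairs A to D had 396, 430, 0 and 3.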

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

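The tests of surrounding normal lung, of age and of the signs of pairs, and the fits within slides, were chosen after the endothelial result was seen, and the other tests in this part before their results were seen.

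Single arrays stood far from the other 5 of their dye orientation in 12 of 304 groups of 6 arrays, and chance gives about 1 in 20 such groups. On replicate 12 Lyve1 was at 0.45 against -1.61 to -0.96 on the others, and Nkd1 at -2.78 against -1.39 to -0.69. On replicate 6 Aurkb was at 1.90 against -0.26 to 0.55, and the red cell and platelet median at 0.080 against -0.21 to -0.11. Tyms was at 0.66 on replicate 9 against 0.43 to 0.51, Gclc at -0.047 on replicate 5 against -1.44 to -1.02, and Piwil2 at -1.01 on replicate 7 against -0.12 to 0.15. The hypoxia and glycolysis median was -0.66 on replicate 2 against -0.24 to -0.0093, and the lipid synthesis median -0.73 on replicate 4 against 0.091 to 0.21. On replicate 11 Dnaic1 was at -0.60 against -0.15 to 0.095, the club cell median at -3.08 against -0.32 to 0.76 and the ciliated median at -2.07 against 0.021 to 0.50.

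Between the pairs, 68 genes differed in their KO over WT ratio by limma's F test. The adjusted p was 1.34e-05 for Pttg1, 7.47e-05 for Pla2g4b, 0.00119 for Rrp7a, 0.00162 for Bet1l, 0.00162 for Ywhaz, 0.00293 for Ifi202b and 0.0289 for Hba-a1. For the Y-linked genes it was 0.00293 (Ddx3y) and 0.0190 (Uty), with pair C setting a male KO against a female WT animal.

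Endothelial markers were lower in KO tumours, and 1 of 100 drawn assignments of KO and WT signs to the 12 arrays, the real one, gave the list so small a p (-log10 p of 45.3, highest other 15.9). That test takes single arrays as units. Arrays of a pair may share animals, so it cannot exclude chance differences between the animals. With the 4 pairs as units the 8 patterns of signs are too few for a share under 0.05 (real -log10 p of 44.5, highest other 6.14). Pairs B and C, with KO animals of the same age and sex in the labels, may not be independent units. More surrounding normal lung in the WT samples as the whole cause would lower alveolar type 1 markers as far. That holds only if the tumour cells did not make these markers, which was not tested. Alveolar type 1 array medians averaged -0.21 ± 0.38 (SD) against -0.71 ± 0.20 for endothelial markers. The endothelial medians lay lower on 10 of 12 arrays (exact two-sided sign-flip p = 0.00488, with arrays as units). Of the alveolar type 1 genes 7 had ratios below 0 and 3 above, with Spock2 at -0.87, Igfbp2 at -0.89 and Pdpn at 0.36. The comparison therefore cannot decide on normal lung. An age difference of the animals as the whole cause would turn the sign in pair A, the pair with the older KO animal, where the endothelial median was -0.59 and so below 0 as in pairs B, C and D. Surrounding normal lung stays open, and the alveolar type 1 list was lower within slide 1 (-0.12) and slide 2 (-0.31). Also open are the untested hypotheses that KO tumours may have held fewer vessels or differed in size or grade, which the labels do not give.

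Airway markers were far lower in KO than in WT RNA on replicate 11. Its endothelial (-1.14), lymphatic (-0.91) and smooth muscle and pericyte (-0.93) medians were also the lowest of the 12 arrays, while by the same gap criterion, which a fault across the whole array would exceed on several lists, it stood apart on 0 of 42 other lists. A candidate source is airway epithelium in the WT tissue of that array, for which the club cell median level was 17.1, against at most 13.6 in the other 23 samples of RNA, and the ciliated median 9.81 against at most 8.06. Of their most abundant genes, Selenbp1 was at 17.8 (at most 17.4 elsewhere), Cbr2 at 18.6 (17.8), Tppp3 at 13.1 (10.3) and Tekt4 at 11.0 (9.73), and 0 of 12 club and 0 of 14 ciliated genes belonged to another list. Lung tissue holds these cells, so a piece of airway, with or without its vessels, in the sample and a difference between the tumours remain open.

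Genes that differed between pairs may in part mark parental alleles that differ between these C57/129 animals. Of 54 such autosomal genes, 9 lay within 10 tested genes of another, against a mean of 3.39 in 10000 random sets (highest 15, one-sided permutation p = 0.0273). Alleles linked to the targeted Dnmt3a allele could instead add called genes near Dnmt3a. There 3 of the 50 nearest tested genes (6%) were called against 11.1% of 17350 others (one-sided Fisher exact p = 0.927). With that share of calls elsewhere a few linked genes would not stand out, so the test cannot exclude them. Coregulated neighbours, other differences between the animals, and the slides and dye orientations of the pairs stay open, as untested.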

How the results depend on the processing

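The fits with local backgrounds as deposited, with a dye term per slide, without replicates 5 and 11 and within each slide were chosen after results were seen, and the other alternatives before. Over the 36 settings the median of all genes stayed between -0.012 and 0.0090. The count of 2173 changed genes became 48 with the mean of each pair as 1 value, which had fewer values per gene and no dye term. It became 546 (263 higher, 283 lower) with pairs A and B alone, and 0, 1 and 0 within slides 1, 2 and 3, also with fewer values per gene. It was 146 with an absolute log2 ratio of at least 1, 578 (248 higher, 330 lower) at an adjusted p under 0.01 and 5285 unadjusted. With arrays or pairs left out it ranged from 696 (without pair A) to 2262, with 1024 without pair B, 1259 without pair C, 1265 without pair D and 1394, 1448 and 1387 without replicates 3, 7 and 12. It was 1930 with median centring and 1484 with local backgrounds as deposited, within 1.5 times. Dnmt3a at -0.21 lost its call with local backgrounds as deposited (-0.15, adjusted p = 0.0677), pair means (-0.23, adjusted p = 0.179), pairs A and B (-0.17, adjusted p = 0.151) and within slides (-0.18, -0.16 and -0.29), within an adjusted p range of 0.000462 to 0.460. With arrays or pairs left out it ranged from -0.23 to -0.18, and the call ended without pair A (adjusted p = 0.0502) and without pair B (adjusted p = 0.0727). Of 45 lists, 18 shifted, against 8 with pairs A and B, 4 with an estimated correlation, 11 and 9 within slides 1 and 2, and 12 to 20 with arrays or pairs left out. Genes that differed between pairs numbered 68, against 168 with median centring and 16 with local backgrounds as deposited. Calls within pairs A to D (1024, 227, 22 and 60) became 396, 430, 0 and 3 with local backgrounds as deposited. Pair C had 94 and pair D 1635 with median centring, and they had 42 and 135 with Agilent's processed signals. Directions reversed for Ereg with the mean of its probes (-0.11, adjusted p = 0.676) and for Ywhaz without pair A (0.77, adjusted p = 0.0397, range with arrays or pairs left out -0.96 to 0.77). List medians reversed for MHC class II within slide 3 (-0.20) and, within slide 2, for red cell (0.037), hypoxia (0.022), ribosomal (-0.024) and gastric lists (0.85, adjusted p = 7.60e-05). The proliferation median reversed within slide 1 (-0.038). Of the 18 shifted lists, 9 lost their call and 0 changed sign with some array or pair left out, and 14 lost it within some slide. Of the 27 lists without a call, 16 changed the sign of their median with some array or pair left out, among them the ciliated list (-0.16) without replicate 11 (0.023) and the club list (-0.21) without pair D (0.056). Apart from the smaller numbers of values, the cause was not tested. Over all settings, other results of named genes were the same in 4708 comparisons, weaker in 699 and stronger in 51, and those of lists in 1633, 94 and 27. The same covers results without a call that changed sign and stayed without one, in 22 comparisons of genes and 114 of lists. Among these genes were Pttg1 (0.30, and -0.55 without pair B), Pla2g4b (0.35, and -0.56 without pair A) and Dnmt1 (-0.056, and 0.061 without pair A), while 0 of the 115 called genes below changed sign with an array or pair left out. Of 115 called named genes besides Dnmt3a, 79 kept the call with each single array left out, and 105 lost it with pair means, 75 without pair A, 58 without pair B, 45 without pair C, 40 without pair D and 29 without replicate 12. The lower share of probes well above background on slide 3 limits pairs C and D.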

Other observations

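The patterns of signs by pair and the fits within slides were added, and the ratio of Eif2s3y was singled out, after results were seen, and the other tests in this part were chosen before.

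Single Wnt target genes fell, while the list missed the threshold of the preset test. Of 14 measured, 4 fell and 0 rose (5 lower adjusted over the list alone), namely the pathway inhibitors Axin2 (log2 ratio -0.50 ± 0.083, SE, n = 12 arrays) and Nkd1 (-1.30 ± 0.29), the transcription factor Lef1 (-0.77 ± 0.14) and the cyclin Ccnd1 (-0.58 ± 0.15). Axin2 and Lef1 were lower on 12 of 12 arrays. Without pair A the calls of Lef1 (-0.51, adjusted p = 0.0633) and Ccnd1 (-0.27, adjusted p = 0.240) ended, the latter also without single arrays such as replicate 12 (-0.57, adjusted p = 0.0611). The list had a median of -0.050 (adjusted p = 0.0759, and adjusted p = 0.431 with an estimated correlation). It passed by fry, which compares its genes with no others (adjusted p = 0.0313). By the preset test it passed within slide 1 (-0.17, adjusted p = 8.93e-05), without replicate 5, 8 or 10 (medians -0.056, -0.054 and -0.043, adjusted p = 0.0452, 0.0362 and 0.0480) and without pair B (-0.087, adjusted p = 0.0171). Of 17 immediate early and heat shock genes 5 fell and 2 rose (5 and 3 adjusted over the list alone). The AP-1 subunit Jund (-0.51 ± 0.059) and the phosphatase Dusp1 (-0.91 ± 0.13) were lower on 12 of 12 arrays, the chaperone Hspa1a fell by 1.13 ± 0.23 and Egr1 rose (0.81 ± 0.17). Their median was -0.12 (adjusted p = 0.143, and adjusted p = 0.327 with an estimated correlation, and adjusted p = 0.0175 by fry), and it was -0.028 without replicate 4, -0.060 without replicate 9 and -0.033 without pair A. Without pair B that median was -0.19.

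Over the 12 arrays, adhesion, lipid and cytokine genes did not shift as lists. Of 34 cell adhesion genes 3 rose and 3 fell (5 and 5 adjusted over the list alone). The hemidesmosome integrin Itgb4 (1.06 ± 0.21) and P-cadherin (Cdh3, 0.27 ± 0.056) rose, and the fibronectin receptor chain Itga5 (-0.22 ± 0.041) and Cdh11 (-0.56 ± 0.13) fell. The adhesion median was -0.048, the mean 0.018 and the test direction lower (adjusted p = 0.730). Of 18 genes of lipid synthesis and uptake 2 rose and 2 fell, with the same counts adjusted over the list alone. The fatty acid elongase Elovl6 rose (0.98 ± 0.24), and the desaturase Scd1 (-1.07 ± 0.26) and the acyl-CoA synthetase Acsl1 (-0.49 ± 0.11) fell. The lipid median was 0.069, the mean 0.00011 and the test direction lower (adjusted p = 0.996). Of 23 inflammatory cytokines and chemokines, Ccl6 (-1.12 ± 0.21), Csf1 (-0.38 ± 0.090) and Csf2 (-0.63 ± 0.17) fell, also when adjusted over the list alone, at a list median of -0.075 (adjusted p = 0.264). The cytokine list was lower within slide 3 (-0.47, adjusted p = 1.71e-06), and without pair D its median was 0.061. The Elovl6 ratio was 0.63 without pair B (adjusted p = 0.244) and the Csf1 ratio -0.24 without pair D, and single arrays ended the calls of Elovl6 (0.92 without replicate 12, adjusted p = 0.0595), Scd1 (-0.98 without replicate 9, adjusted p = 0.0590), Csf1 (-0.36 without replicate 9, adjusted p = 0.0513) and Csf2 (-0.54 without replicate 12, adjusted p = 0.0761). The adhesion median was 0.030 without pair A and -0.15 without pair B, and the lipid median -0.037 without pair B and 0.14 without replicate 4.

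Eif2s3y, on the Y chromosome, had a log2 KO over WT ratio of 2.81 on replicate 5, before the dye term was removed, although both animals of that array are labelled male. Its ratios on the other arrays of pair B lay between -0.46 and 0.48, and on replicate 5 the Ddx3y probes stood at 0.25 and 0.12. No explanation of this was tested.

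For the count of changed genes, 1 of 100 drawn assignments of KO and WT signs to the 12 arrays, the real one, gave so many calls (2170 in that refit, highest other 51). With single arrays as units, which may share animals within a pair, this cannot exclude chance differences between the animals. With the pairs as units there are 8 patterns of signs, too few for a share under 0.05, and the real pattern gave 49 genes against a highest other of 0. Pairs B and C may share a KO animal.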
